A study of Mus musculus with 305 samples.

How the data were processed

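Each of the 305 deposited samples is 1 cell. Per the labels' protocols, bone marrow was enriched with CD117 beads, sorted, and single cells were separated on a Fluidigm C1 instrument; cDNA was made with a SMARTer kit and libraries with Nextera XT. This chemistry covers full-length transcripts and carries no molecular identifiers, so amplification copies cannot be removed by molecule. Per the submitters' processing notes, reads were handled with Bowtie2 and RSEM on the mm9 build. Versions and gene annotation are not given in the sources used here. RSEM divides reads among near-identical genes, so values of paralogs such as the H2B histones or Eno1 and Eno1b are uncertain.

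The deposited table holds log2 values of TPM (transcript abundance scaled to a fixed total per cell) plus 1 for 23879 genes. Taken back to TPM, each cell sums to between 990425 and 999902, and 100% of values above 0 fall on steps of 0.01 TPM within 0.02 of a step. TPM keeps no depth, so the number of genes detected is the measure of library quality used, and no interval that needs read counts is given. Of the genes, 9085 are 0 in every cell. The mitochondrially encoded genes are not in the table, and that list was not analysed here. No 2 columns are identical. No coordinates are given, because the reference used here is of a later build than the authors' alignment.

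Groups were taken from the sample titles, and sequencing run and capture label from the sample descriptions. There are 4 runs and 6 capture labels, and sSLAM and T-qSLAM share neither with any other group. No animal, donor or culture is named, so each group was treated as 1 sample: no test, p-value or count of changed genes is given. Shares of cells carry exact Clopper-Pearson 95% intervals, which cover counting error only. A gene was detected in a cell at 1 TPM or more. The plan made before the data were examined foresaw either TPM or log values, and the deposited log2(TPM + 1) was used unaltered, which means a pseudocount of 1 TPM. A difference on this scale understates that of low genes.

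For each of 9 differences between groups, means over cells were subtracted. A list member was measured if detected in at least 10% of the cells of either group. The median difference of the measured members was placed among the medians of 10000 random lists of the same size, drawn from other genes in 20 bins of mean expression; both medians and the percentile are given, and members beyond 1 either way are counted. The 31 gene lists and the named-gene rule were fixed before the data were examined. Named were the 10 highest and 10 lowest genes by difference among those detected in at least 25% of cells of the higher group, leaving out predicted, accession-named and small RNA genes; up to 4 members per list with the largest differences; and 28 genes fixed by name. The text prints part of these. No doublet caller was run and all 305 cells were kept, so doublets are not excluded; 1 aSLAM cell held both Xist and a Y-linked transcript. No clusters were made.

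The arithmetic of the steps was checked with shifts added to the data. Shifts of 1 and 2 were added to 100 genes each in a random part of the sSLAM cells (8638 genes) and of the T-divSLAM cells (8838 genes). The mean recovered shifts were 0.83 and 1.91 in sSLAM and 0.96 and 1.87 in T-divSLAM. Lists of 30 shifted genes reached percentile 100 in each case. This recovery was set by construction, apart from the difference between the parts. Loss of detection and unequal gene number were not simulated, so it does not show how the steps handle them. Over 50 random divisions of 1 group into near-equal parts with no shift, the fixed lists fell outside percentiles 2.5 to 97.5 in 17.9% of cases in sSLAM and 10.4% in T-divSLAM. Random lists did so in 10% and 4%. The reason was not tested. Percentiles therefore over-call the fixed lists, describe these libraries only and are not error rates.

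Alternatives planned beforehand were pseudocounts of 0.1 and 10, no filter on low values, the ratio of arithmetic means, median-of-ratios rescaling over 3333 genes, removal of ribosomal protein genes with rescaling, leaving out 5 cells with few genes (more than 3 median absolute deviations under the group median), and aSLAM cells of either capture alone. Chosen after seeing the data were a comparison within bins of 500 genes detected, removal of the trend on transcript length (lowess, fraction 0.3, median lengths of GENCODE M21 transcripts, used for lengths only), and restriction to cells with a Y-linked transcript or with Xist. Under alternatives, 1000 random lists were drawn. In a first run of the alternatives the value followed was the raw list median. After its reversals were seen, the value was redefined as the list median minus that of matched lists, the quantity behind each percentile; the sensitivity part gives the count of sign changes under both forms. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.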

Results

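The transcriptomes of 305 single mouse cells were profiled. All cells were C57BL/6 bone marrow stem cells with the surface phenotype Lin- Sca1+ CD117+ CD150+ CD48-, called LSK-SLAM cells, a fraction enriched for long-term repopulating hematopoietic stem cells. The labels divide them into sSLAM (n = 59 cells), aSLAM (n = 40), divSLAM (n = 55), T-qSLAM (n = 56), T-aSLAM (n = 31) and T-divSLAM (n = 64). They do not spell out the prefixes, so the names are used as given. The title of the series concerns developmental hierarchies, and no question is stated for a particular pair of groups. No animal or culture is named, so each group counts as 1 sample without replication. No test was run, ± is the SD over the cells of a group, and "higher" or "lower" describes these libraries only. Expression is given as mean log2(TPM + 1), and differences are on that scale. Read depth is unknown.

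The groups differed widely in how many genes were seen per cell. At 1 TPM or more, 3393 ± 604 genes were detected in sSLAM cells, 5804 ± 368 in aSLAM and 5225 ± 479 in divSLAM. The T groups had 2945 ± 476 genes in T-qSLAM, 4438 ± 645 in T-aSLAM and 3945 ± 1095 in T-divSLAM. No sSLAM cell exceeded 4878 genes and no aSLAM cell had fewer than 5247. The typical gene therefore differed between groups too, by a median of 0.85 for aSLAM minus sSLAM over the 10380 genes compared, and each gene list below is set against 10000 random lists matched on mean expression. The sSLAM and T-qSLAM cells were each alone in a sequencing run, so for them group and run cannot be told apart. The sex-linked transcripts also varied by group. Xist, expressed from the inactive X chromosome, was detected in 0 sSLAM and 0 T-qSLAM cells, in 20 aSLAM and 24 divSLAM cells, and in 28 T-aSLAM and 43 T-divSLAM cells. A Y-linked transcript was detected in 54, 41, 20, 29, 0 and 0 cells of sSLAM, T-qSLAM, aSLAM, divSLAM, T-aSLAM and T-divSLAM. Both were detected in 1 aSLAM cell and in 0 other cells. The aSLAM and divSLAM groups thus mixed cells of both sexes, and so of more than 1 animal, but which cells share an animal is not given.

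**Figure D1:**
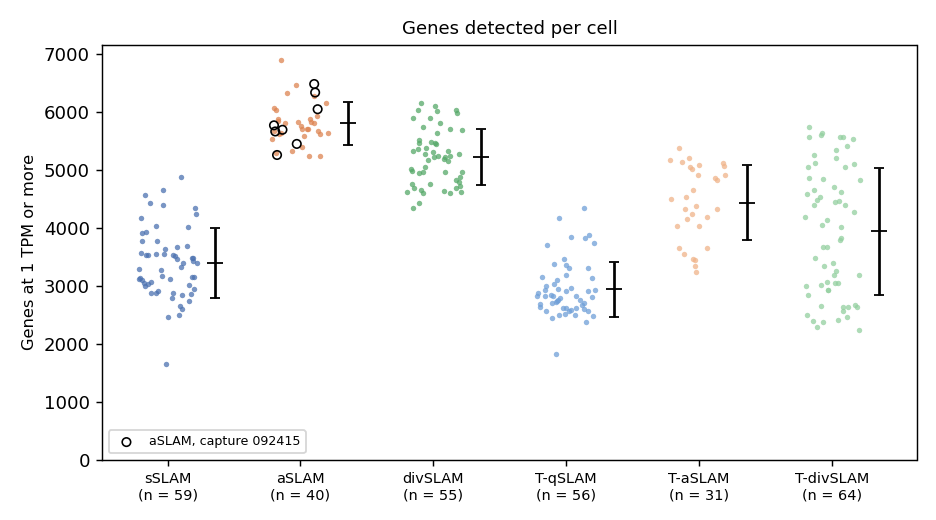
Genes detected per cell at 1 TPM or more (vertical axis) for the 6 groups. Each point is 1 cell, the bar beside it is the mean with its SD, and open circles mark the 8 aSLAM cells with capture label 092415; the lowest aSLAM cell (5247 genes) lies above the highest sSLAM cell (4878 genes).

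Transcripts of dividing cells were detected in smaller shares of sSLAM and T-qSLAM cells than of the other groups. Mki67, a proliferation antigen, was detected in 16.9% of sSLAM cells (95% exact binomial interval 8.44 to 29.0%) and 28.6% of T-qSLAM cells (17.3 to 42.2%). Its share was 97.5% in aSLAM (86.8 to 99.9%), 81.8% in divSLAM (69.1 to 90.9%), 61.3% in T-aSLAM (42.2 to 78.2%) and 82.8% in T-divSLAM (71.3 to 91.1%). Ccnb1, the mitotic cyclin B1, was detected in 13.6% of sSLAM, 95.0% of aSLAM, 78.2% of divSLAM, 10.7% of T-qSLAM, 51.6% of T-aSLAM and 82.8% of T-divSLAM cells. At least 5 of the G2/M genes were detected in 30.5% of sSLAM cells (19.2 to 43.9%), 33.9% of T-qSLAM cells (21.8 to 47.8%), 80.6% of T-aSLAM cells (62.5 to 92.5%) and every cell of aSLAM, divSLAM and T-divSLAM. Mcm5, a subunit of the replicative helicase, was detected in 42.4% of sSLAM and 44.6% of T-qSLAM cells, and in 97.5, 96.4, 83.9 and 81.3% of aSLAM, divSLAM, T-aSLAM and T-divSLAM cells. The intervals cover counting error only, and the shares were not compared at equal gene number, where the G2/M list lay below matched lists for divSLAM minus sSLAM (percentile 2.4) and T-aSLAM minus T-qSLAM (percentile 0) and above them for T-divSLAM minus T-qSLAM (percentile 100). For divSLAM minus sSLAM and T-aSLAM minus T-qSLAM, equal gene number leaves the lowest cells of the first group and the highest of the second by genes detected. The G2/M share depended on the detection limit where few genes were seen, and counting any value above 0 gave 84.7% of sSLAM and 62.5% of T-qSLAM cells.

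In aSLAM compared with sSLAM, cell cycle, mitochondrial and sterol genes were higher, while immediate early and stem cell genes were lower. Of 35 G2/M genes, 34 were higher by at least 1 and 0 lower, with a median difference of 4.70 against 1.82 for matched lists (percentile 100). Ccnb1 averaged 7.46 ± 2.80 in aSLAM and 1.02 ± 2.73 in sSLAM, and Kpna2, a nuclear import receptor, 9.69 ± 1.54 and 2.16 ± 3.35. The G1/S list had 30 of 32 genes higher (median 3.53 against 1.97), led by Rrm2, a subunit of ribonucleotide reductase, at 8.67 ± 1.17 and 1.34 ± 2.78. The histone chaperone gene Asf1b (7.39 ± 1.90 and 0.89 ± 2.60), the mitotic kinase gene Pbk (8.57 ± 1.10 and 1.20 ± 3.00) and the tubulin gene Tuba1c (9.68 ± 0.75 and 3.39 ± 3.53) were also among the 10 with the largest differences.

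Metabolic lists were higher in aSLAM as well. The nuclear-encoded respiratory chain had 66 of 73 genes higher by at least 1 and 0 lower (median 2.54 against 1.68, percentile 100), including Cyc1, encoding cytochrome c1 (difference 5.68), and Cox5a (4.59). All 21 tricarboxylic acid cycle genes were higher (median 3.35 against 2.28), with Fh1 at 5.07 and Cs, citrate synthase, at 4.58. Cholesterol synthesis had 19 of 20 genes higher (median 3.56 against 1.77, percentile 100), and Fdps, farnesyl diphosphate synthase, averaged 8.56 ± 1.07 in aSLAM and 2.03 ± 3.73 in sSLAM. Mitochondrial biogenesis and import (2.66 against 1.45), nucleolar ribosome biogenesis (3.02 against 2.01) and glycolysis (2.39 against 1.58) also exceeded matched lists at percentiles of 98.3 or more. The 75 cytosolic ribosomal protein genes did not share this shift, with a median of -0.25 against 1.64 (percentile 0). Mitochondrial dynamics and mitophagy (1.14 against 1.43), fatty acid oxidation (1.81 against 1.66), lysosome (1.72 against 1.56), redox defence (1.61 against 1.68), the unfolded protein response (2.09 against 1.54), DNA repair (1.48 against 1.14), p53 targets (0.75 against 0.72), G0/G1 regulators (1.11 against 1.03), megakaryocyte markers (0.88 against 0.58) and genes reported higher in aged stem cells (0.89 against 0.66) lay within the middle 95% of matched lists.

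The immediate early list, genes induced within minutes by stimulation or tissue dissociation, was lower in aSLAM than in sSLAM, with 12 of 19 genes lower by at least 1 and 0 higher (median -1.12 against 1.24, percentile 0). Fos averaged 1.55 ± 2.32 in aSLAM and 9.21 ± 3.34 in sSLAM, Dusp1 1.55 ± 2.28 and 7.67 ± 3.61, Jun 0.80 ± 1.40 and 5.85 ± 2.52, and Zfp36 1.99 ± 2.62 and 6.77 ± 3.65. Stem cell identity genes had 12 of 29 members lower and 3 higher (median -0.74 against 1.28, percentile 0). Hlf, a transcription factor of long-term stem cells, averaged 2.14 ± 2.04 in aSLAM and 5.99 ± 2.80 in sSLAM, and Mpl, the thrombopoietin receptor, 6.14 ± 2.78 and 8.66 ± 2.47. Gfi1b was the largest exception (difference 3.92). Prtn3, a granule protease of myeloid progenitors, averaged 0.87 ± 1.76 and 6.26 ± 3.38. It led a granulocyte and monocyte list of 5 measured genes of which 4 were lower. The type I interferon list had a median of -0.15 against 0.91 (percentile 0). Because the genes detected per cell did not overlap, aSLAM and sSLAM could not be compared at equal gene number.

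The divSLAM cells differed from sSLAM in nearly the same lists. All 32 G1/S genes and all 34 measured G2/M genes were higher by at least 1, with medians of 3.56 against 1.70 and 3.33 against 1.11 for matched lists. Rrm2 averaged 8.73 ± 1.49 in divSLAM and 1.34 ± 2.78 in sSLAM. The respiratory chain (68 of 73 genes higher, median 2.61 against 1.62) and cholesterol synthesis (17 of 20, median 3.05 against 1.25) were higher too. The immediate early list was lower (14 of 19 genes, median -1.64 against 0.92), with Fos at 0.55 ± 1.86 and 9.21 ± 3.34 and Egr1 at 2.77 ± 3.12 and 8.65 ± 3.97. Stem cell identity was lower in 14 of 29 genes (median -0.79 against 1.07), and Mpl averaged 4.62 ± 3.31 in divSLAM. Granulocyte and monocyte markers were lower in 4 of 4 measured genes (-1.89 against 1.61, percentile 0.02), and long-lived nuclear RNA had a median of -0.99 against 0.51 (percentile 0.01). Cd48, whose protein the sort gate excludes, averaged 3.45 ± 4.18 in divSLAM and 0.60 ± 1.99 in sSLAM. Among the 21 divSLAM and 10 sSLAM cells that overlapped in genes detected, the G2/M median was -0.59 against 0.06 and the G1/S median 0.55 against 0.33, so neither cycle list stood above matched genes there. These were the divSLAM cells with the fewest genes and the sSLAM cells with the most. A gene number effect therefore cannot be told apart from the choice of cells. The medians in those cells were -0.42 against 0.19 for stem cell identity (percentile 0.8), -1.59 against 0.09 for immediate early genes, 0.88 against 0.28 for the respiratory chain, -1.03 against 0.29 for granulocyte and monocyte markers (percentile 4.9) and -0.30 against 0.08 for long-lived nuclear RNA (percentile 19).

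The divSLAM and aSLAM cells shared a sequencing run and differed in cell cycle lists, among others. The G2/M list was lower in divSLAM in 24 of 35 genes and higher by at least 1 in 0 (median -1.35 against -0.37, percentile 0). Plk1, a mitotic kinase, averaged 3.54 ± 3.75 in divSLAM and 6.08 ± 2.88 in aSLAM, and Nusap1, a spindle protein, 2.82 ± 3.09 and 5.34 ± 2.76. The G1/S list had a median of 0.18 against -0.25 (percentile 100), and Ccne2, cyclin E2, averaged 3.73 ± 3.33 in divSLAM and 1.91 ± 2.55 in aSLAM. The 75 ribosomal protein genes had a median of 0.14 against -0.06 (percentile 100), granulocyte and monocyte markers of 0.32 against -0.17 and sex chromosome transcripts of 0.31 against -0.20. The respiratory chain did not separate the groups, since 0 of 73 genes differed by 1 (median -0.02 against -0.07). Lower in divSLAM were the glucose transporter gene Slc2a3 (3.45 ± 3.08 and 6.05 ± 2.57) and Gzmb, granzyme B (1.39 ± 2.36 and 3.86 ± 5.16).

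Capture label divides this comparison, because 32 aSLAM cells carry label 120215 and 8 carry 092415, the label of all divSLAM cells. The names of these 8 begin an alphabetical run that continues with divSLAM cells, so their group label, kept as given, is in doubt, and with it each value within 092415. Within 092415, the G2/M median was -2.76 against -0.42, and it was -0.999 against -0.382 with the 120215 cells alone. The G1/S median was 0.38 within 092415 and 0.12 with 120215. Cd34 averaged 6.42 ± 3.13 in divSLAM, 3.63 ± 3.25 in the aSLAM cells of 120215 and 7.54 ± 1.34 in those of 092415. Eno1b, a near-copy of Eno1 whose reads are hard to assign, averaged 2.67 ± 3.50, 7.64 ± 2.33 and 1.83 ± 3.79. Cd34 and Eno1b were the extremes of the genes ranked by the difference between the captures, so a gap between captures was set by that choice. Their differences between divSLAM and the aSLAM cells of 092415 were smaller than the SD over cells. Genes reported higher in aged stem cells were lower in divSLAM overall (median -0.57 against -0.17, percentile 0.45), but within 092415 the median was 0.63 against -0.16. Compared with the aSLAM cells of 092415, those of 120215 had lower G2/M transcripts (median -1.79 against -0.08) and higher unfolded protein response transcripts (0.69 against -0.08). At equal gene number the G2/M median of divSLAM minus aSLAM was -0.27 against -0.05 (percentile 4.7) and the G1/S median 0.12 against -0.01 (percentile 95.1), while the aged-cell list (-0.47 against -0.01, percentile 0) and ribosomal protein genes (0.14 against 0.03, percentile 100) stayed apart and granulocyte and monocyte markers (0.05 against -0.03, percentile 62.2) and sex chromosome transcripts (0.18 against -0.01, percentile 72.3) did not.

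**Figure D2:**
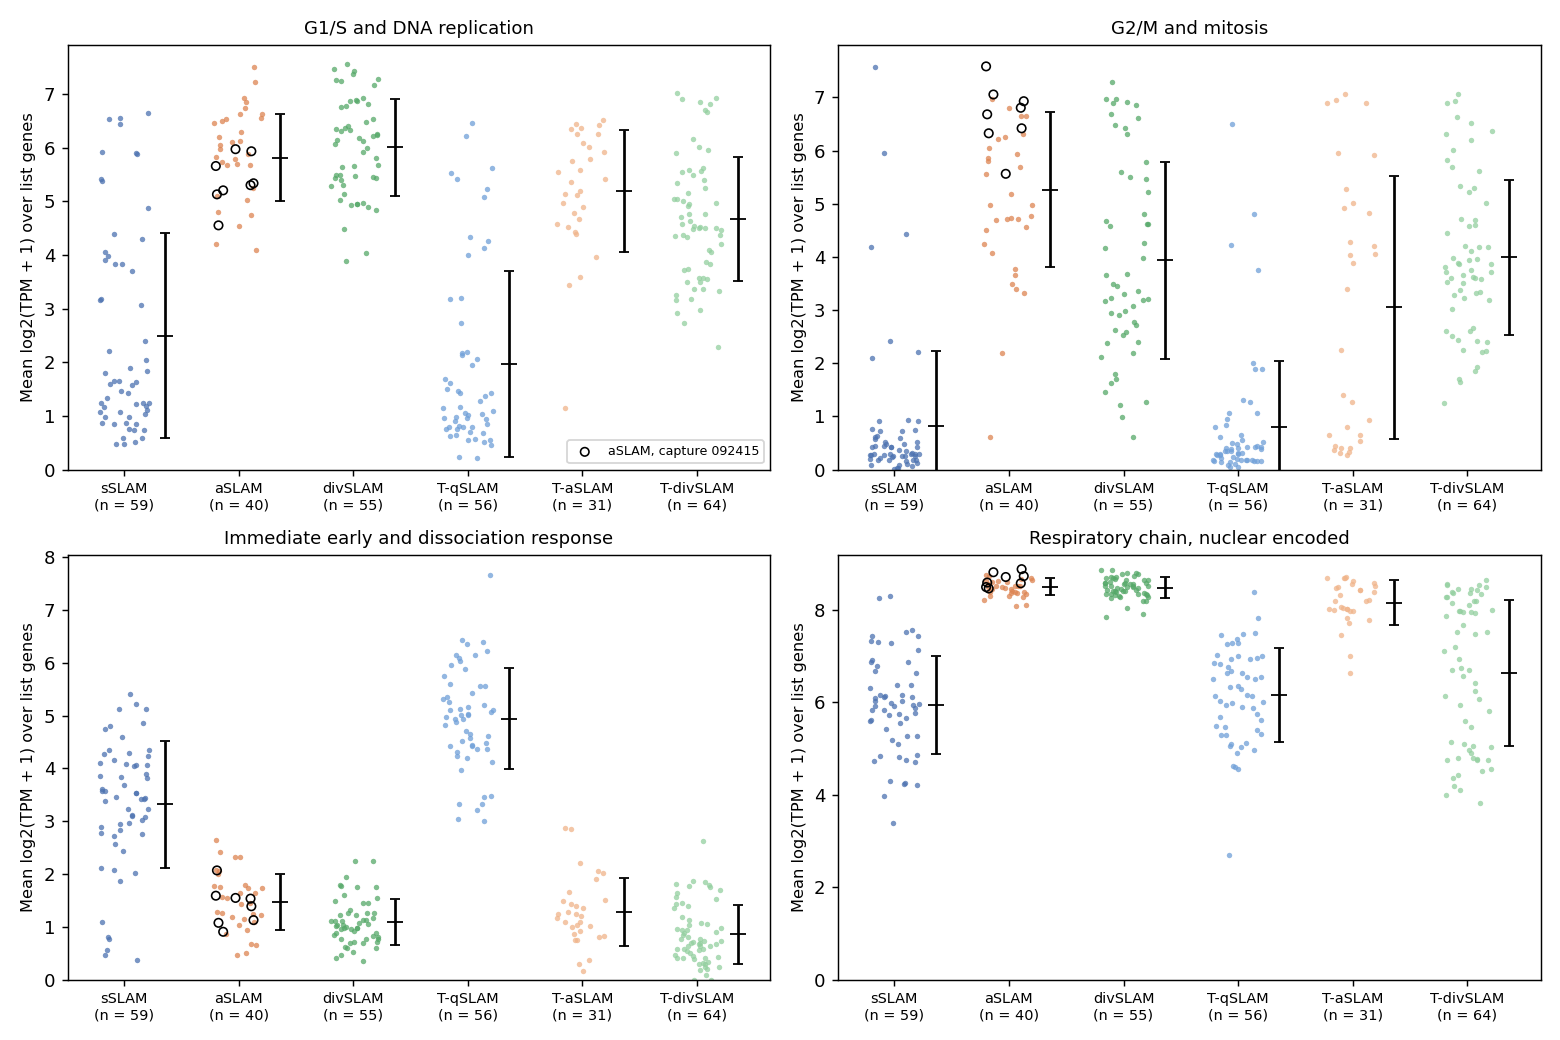
Mean log2(TPM + 1) over the genes of 4 lists in each cell (vertical axes) for the 6 groups, with 1 point per cell, the mean and SD beside each group, and open circles for the 8 aSLAM cells with capture label 092415. Immediate early scores are highest in T-qSLAM (4.94 ± 0.96) and sSLAM (3.32 ± 1.21), and respiratory chain scores spread most in T-divSLAM (6.64 ± 1.58).

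Among the T groups, T-aSLAM had higher cell cycle transcripts than T-qSLAM and far lower immediate early transcripts. T-qSLAM differed from T-aSLAM and T-divSLAM in sequencing run, capture label and sex-linked transcripts. Comparisons with T-qSLAM cannot be separated from these. Of 22 immediate early genes, 19 were lower by at least 1 and 0 higher (median -3.30 against 1.16, percentile 0). Fos averaged 1.56 ± 2.64 in T-aSLAM and 9.98 ± 2.49 in T-qSLAM, Jun 1.24 ± 1.80 and 8.93 ± 1.76, and Nr4a1, an orphan nuclear receptor, 0.43 ± 1.49 and 7.25 ± 2.81. The antiproliferative gene Btg2 averaged 1.07 ± 2.49 and 7.54 ± 4.37. The G1/S list was higher in 30 of 32 genes (median 3.30 against 1.52) and the G2/M list in 32 of 34 (2.14 against 1.01), with Rrm1 at 8.34 ± 1.31 and 2.87 ± 3.69 and Rfc4, a clamp loader subunit, at 7.15 ± 2.79 and 1.60 ± 3.30. The respiratory chain was higher in 60 of 73 genes (median 2.10 against 1.38), and DNA repair genes in 18 of 24 (1.38 against 0.73, percentile 99.9). Cholesterol synthesis was higher in 15 of 20 genes (1.75 against 1.05, percentile 98.6) and erythroid markers in 5 of 8 (1.81 against 0.74, percentile 99.9). Lower than matched lists were granulocyte and monocyte markers (-1.19 against 1.43) and long-lived nuclear RNA (-0.90 against 0.87, percentile 0.13). Idi1 of the sterol pathway averaged 7.46 ± 2.43 and 1.37 ± 2.88, and S100a6, a calcium-binding protein, 9.19 ± 1.20 and 3.80 ± 3.85. Histone H2B genes were lower in T-aSLAM, with Hist1h2bf at 2.43 ± 2.49 and 9.96 ± 1.82, although these near-identical copies share reads. Among the 15 T-aSLAM and 17 T-qSLAM cells that overlapped in genes detected, the G2/M median was -1.004 against 0.046, the G1/S median 0.37 against 0.25, and the immediate early median -3.70 against 0.16. These were the T-aSLAM cells with the fewest genes and the T-qSLAM cells with the most, so they need not represent their groups. In those cells DNA repair (0.32 against 0.00, percentile 89.2), cholesterol synthesis (0.61 against 0.12, percentile 93.6) and erythroid markers (0.48 against 0.04, percentile 86.8) did not stand apart, while granulocyte and monocyte markers (-1.59 against 0.20, percentile 0.8) and long-lived nuclear RNA (-0.97 against 0.11, percentile 2) did.

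T-divSLAM compared with T-qSLAM showed the same cell cycle and immediate early directions by median. The G2/M list was higher in 34 of 35 genes (median 3.01 against 0.85) and the G1/S list in 28 of 32 (2.88 against 0.84). Top2a, the topoisomerase of dividing cells, averaged 7.66 ± 2.39 in T-divSLAM and 1.69 ± 3.05 in T-qSLAM, and Cdk1, the mitotic kinase, 6.36 ± 3.10 and 1.16 ± 2.56. The immediate early list was lower in 20 of 22 genes (median -3.71 against 0.71), with Fos at 0.53 ± 1.80, Egr1 at 1.82 ± 2.89 and Fosb at 0.10 ± 0.45, against 9.98 ± 2.49, 9.09 ± 2.83 and 6.89 ± 2.71. Pf4, platelet factor 4, averaged 8.62 ± 2.97 and 2.91 ± 4.06. p53 targets had 10 of 17 genes higher (median 1.08 against 0.49, percentile 99.8), including Psrc1 (2.91) and Ccng1 (2.49). Granulocyte and monocyte markers were lower in 4 of 4 measured genes (-1.57 against 0.87, and -2.09 against 0.05 at equal gene number). The respiratory chain did not stand out (median 0.55 against 0.61, percentile 36.3), and 56 of 75 ribosomal protein genes were lower (median -1.19 against 0.51, percentile 0). Among 41 T-divSLAM and 55 T-qSLAM cells overlapping in genes detected, the medians were 2.20 against 0.09 for G2/M, 1.42 against 0.02 for G1/S and -4.15 against 0.05 for immediate early genes, and the respiratory chain was lower in T-divSLAM (-1.08 against -0.25, percentile 0.1).

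T-divSLAM and T-aSLAM shared a sequencing run but not a capture label. Mitotic transcripts were higher in T-divSLAM, with 14 of 35 G2/M genes higher by at least 1 and 0 lower (median 0.82 against -0.53, percentile 100). Ccnb1 averaged 6.81 ± 3.80 in T-divSLAM and 3.83 ± 4.27 in T-aSLAM, and Ube2c, an enzyme of mitotic ubiquitination, 6.47 ± 3.58 and 3.53 ± 4.10. Respiratory chain transcripts were lower in T-divSLAM, in 54 of 73 genes with 0 higher (median -1.51 against -0.81, percentile 0), among them Ndufs8 (-3.04) and Ndufa12 (-2.90) of complex I. Other mitochondrial genes among the 10 lowest were Mrpl28 of the mitochondrial ribosome (4.81 ± 4.09 and 8.76 ± 1.81), Hsd17b10 (5.32 ± 3.94 and 9.01 ± 1.03) and Uqcc2, a complex III assembly factor (4.62 ± 3.69 and 8.44 ± 0.68). The other mitochondrial lists fell less. Their medians were -0.73 for the tricarboxylic acid cycle, -0.50 for fatty acid oxidation, -0.45 for biogenesis and import and -0.40 for dynamics and mitophagy. The median of ribosomal protein genes was -0.69. These medians cover members detected in at least 10% of T-divSLAM, T-aSLAM, divSLAM or aSLAM cells and are given without matched lists. They therefore do not show whether these lists stood apart from genes of like expression, as lists matched to the respiratory chain already had a median of -0.81. Pf4 averaged 8.62 ± 2.97 in T-divSLAM and 3.85 ± 4.30 in T-aSLAM, in a megakaryocyte list with 3 of 12 genes higher and Mpl lower (2.74 ± 3.56 and 5.78 ± 2.98). Pdcd4 (9.67 ± 1.27 and 6.85 ± 1.82) and Gzmb (3.57 ± 4.38 and 1.00 ± 2.58) were also higher in T-divSLAM, and Ly6a, encoding Sca1, was lower (3.32 ± 4.09 and 6.04 ± 4.64). p53 targets had a median of 0.52 against -0.10 and cholesterol synthesis of 0.08 against -0.47 (percentiles 100 and 99.4). At equal gene number the G2/M median was 1.14 against -0.14 and the respiratory chain median -0.68 against -0.36. Short transcripts were lower in T-divSLAM in general (Spearman correlation of difference with transcript length 0.21 across genes), and with that trend removed the respiratory chain median was -1.29 against -0.70.

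The div minus a difference was then set side by side with and without the T label. For G2/M genes it was -1.35 without T and 0.82 with T, and the median per-gene difference between the contrasts was 2.34 against -0.15 for matched lists (percentile 100). For the respiratory chain it was -0.02 without T and -1.51 with T (median -1.52 against -0.77, percentile 0). p53 targets (0.63 against 0.09), megakaryocyte markers (0.59 against -0.05) and cholesterol synthesis (0.37 against -0.21) also lay above matched lists at percentiles of 98.6 or more, and granulocyte and monocyte markers below them (-0.83 against 0.12, percentile 0.58). With only the aSLAM cells of 092415, the capture of divSLAM, p53 targets (0.37 against 0.06, percentile 88.6), megakaryocyte markers (0.165 against -0.157, percentile 88.8) and granulocyte and monocyte markers (-0.27 against -0.08, percentile 26.9) no longer stood apart, while cholesterol synthesis did (0.59 against -0.20, percentile 98.9). The group label of those 8 aSLAM cells is in doubt, so this restriction does not decide whether the differences between contrasts hold. Across 8284 genes, which are not independent replicates, the contrasts correlated weakly (Pearson 0.07, Spearman 0.07). These differences between contrasts were not tested, since each of the 4 groups is 1 sample. At equal gene number the G2/M difference without T was only -0.27 against -0.05 (percentile 4.7).

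Mitotic genes were lower in T-aSLAM than in aSLAM. These groups share neither a sequencing run nor a capture label, so their differences cannot be separated from run or capture. The G2/M list was lower in T-aSLAM in 32 of 35 genes with 0 higher (median -2.27 against -0.86, percentile 0), and Ccnb1 averaged 3.83 ± 4.27 in T-aSLAM and 7.46 ± 2.80 in aSLAM. The tricarboxylic acid cycle (13 of 21 genes lower, median -1.23 against -0.60), mitochondrial biogenesis and import (14 of 27, -1.01 against -0.44) and cholesterol synthesis (13 of 20, -1.38 against -0.67) were lower as well, all at percentiles of 0.22 or less. The respiratory chain was not (median -0.20 against -0.22). Stem cell identity genes had a median of -0.07 against -0.62 (percentile 99.97), with Ly6a at 6.04 ± 4.64 in T-aSLAM and 2.67 ± 3.54 in aSLAM. Nupr1, a stress-response gene, averaged 6.85 ± 3.64 and 3.15 ± 3.31, and the interferon-inducible GTPase genes Tgtp2 (7.71 ± 2.60 and 5.60 ± 3.27) and Iigp1 (2.86 ± 3.45 and 0.81 ± 1.75) were also higher in T-aSLAM. The list of long-lived nuclear RNA, a sign of RNA quality that includes Xist, had a median of 0.61 against -0.27 (percentile 99.94). The G2/M median was -2.06 against -0.84 among cells with Xist. In the 9 T-aSLAM and 7 aSLAM cells of equal gene number it was 0.725 against -0.102, the opposite direction. Those were the T-aSLAM cells with the most genes and the aSLAM cells with the fewest. There stem cell identity (0.07 against -0.04, percentile 68.4), the tricarboxylic acid cycle (-0.06 against 0.00, percentile 40.3), cholesterol synthesis (0.03 against -0.05, percentile 60.5) and long-lived nuclear RNA (0.23 against 0.01, percentile 74.5) did not stand apart, while mitochondrial biogenesis and import did (-0.34 against 0.00, percentile 1.7).

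T-divSLAM compared with divSLAM had lower respiratory chain and nucleolar transcripts, while mitotic transcripts were higher than matched lists. Here too the groups share neither a sequencing run nor a capture label, so run and capture cannot be told apart from the group. The respiratory chain was lower in 65 of 73 genes with 0 higher (median -1.91 against -1.05, percentile 0), including Ndufs8 (-3.27) and Cyc1 (-3.21). Nucleolar ribosome biogenesis was lower in 18 of 29 genes (median -1.472 against -0.9997, percentile 1.3), with Fbl, fibrillarin, at -2.90. The G2/M median was -0.06 against -1.05 (percentile 100), with 3 genes higher and 3 lower. Genes reported higher in aged stem cells had a median of 0.32 against -0.45 (percentile 100) with 5 of 14 higher by at least 1, among them Selp, P-selectin (2.49 ± 3.23 in T-divSLAM and 0.38 ± 1.24 in divSLAM) and Aldh1a1 (1.83). Pf4 averaged 8.62 ± 2.97 and 5.48 ± 4.25, Casp12 4.04 ± 3.82 and 1.28 ± 2.36, and Cdkn1a, the p21 cell cycle inhibitor, 3.04 ± 3.16 and 1.54 ± 2.05. Dynlt1b (4.28 ± 3.99 and 8.68 ± 1.29), the proteasome gene Psmc5 (3.64 ± 3.81 and 7.79 ± 1.94) and Cd34 (difference -3.22) were lower. Among cells with Xist the respiratory chain median was -1.67 against -0.93, and at equal gene number it was -0.33 against -0.16, with a G2/M median of 0.64 against -0.14 (percentile 100). Long-lived nuclear RNA had a median of 0.55 against -0.67 (percentile 99.97).

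T-qSLAM and sSLAM, the groups with the fewest mitotic transcripts, differed in immediate early genes and H2B histone genes, among others. Immediate early genes were higher in T-qSLAM in 12 of 22 and lower in 1 (median 1.13 against -0.22, percentile 100), with Nr4a1 at 7.25 ± 2.81 in T-qSLAM and 1.39 ± 2.10 in sSLAM and Btg2 at 7.54 ± 4.37 and 3.78 ± 4.42. Hist1h2bf averaged 9.96 ± 1.82 and 0.06 ± 0.43, Hist1h2bm 8.94 ± 1.92 and 0.28 ± 1.29, and Hist3h2ba 5.83 ± 1.66 and 0.00 ± 0.00. Summed over 19 H2B genes, which removes the split of reads between copies, the median cell held 2698 TPM in T-qSLAM and 15.5 TPM in sSLAM. The sum does not show which H2B sequence the reads came from, and no other histone family was summed. Stem cell identity was lower in T-qSLAM in 12 of 29 genes with 0 higher (median -0.75 against -0.24, percentile 0.07), with Hlf at 2.31 ± 3.02 and 5.99 ± 2.80 and Mpl at 5.33 ± 4.21 and 8.66 ± 2.47. Myc averaged 2.15 ± 3.21 and 5.41 ± 4.03. Respiratory chain scores were 6.16 ± 1.01 in T-qSLAM and 5.94 ± 1.06 in sSLAM. With the length trend removed the list median was 0.32, where the median of all genes compared was -0.27. Genes reported higher in aged stem cells had a median of 0.46 against -0.28 (percentile 100), led by Aldh1a1 (3.57) and Mt1 (2.79), and megakaryocyte markers of 0.47 against -0.24. The groups come from different sequencing runs and captures, so the difference cannot be separated from either. These values were not taken at equal gene number, which averaged 2945 in T-qSLAM and 3393 in sSLAM. Such a comparison was possible, with 56 T-qSLAM and 56 sSLAM cells overlapping in genes detected. There the median of all genes compared was -0.07, where it was -0.27 over all cells. The list medians at equal gene number are not given here.

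**Figure D3:**
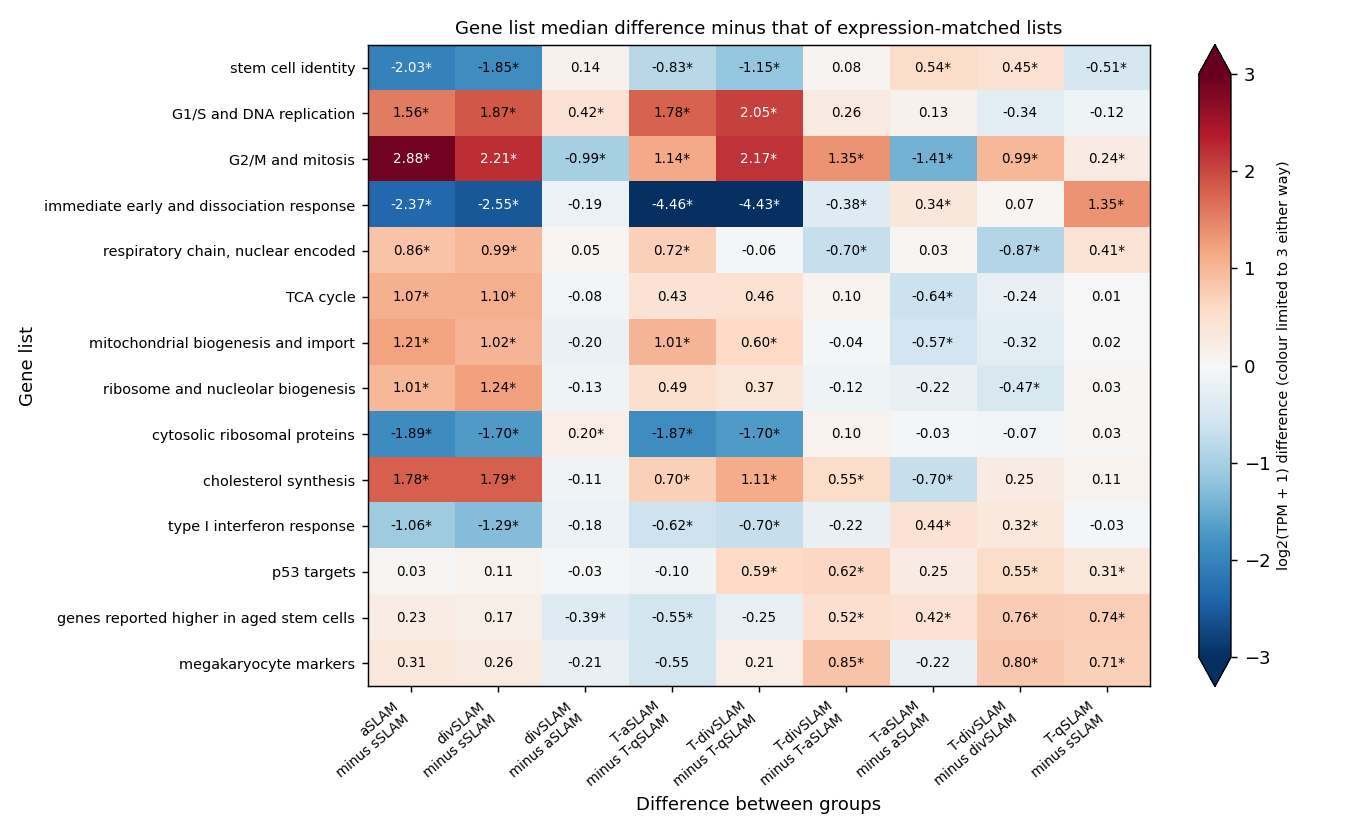
Median difference of 14 gene lists (rows) in the 9 group differences (columns), minus the median of expression-matched random lists, in log2(TPM + 1) units; an asterisk marks a list below percentile 2.5 or above 97.5. The G2/M row is above matched lists for aSLAM minus sSLAM (2.88), below them for divSLAM minus aSLAM (-0.99) and above them for T-divSLAM minus T-aSLAM (1.35).

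Cells within a group also varied to different degrees. The SD of the respiratory chain score was 0.18 over aSLAM cells and 0.22 over divSLAM cells, 0.48 in T-aSLAM, 1.01 in T-qSLAM, 1.06 in sSLAM and 1.58 in T-divSLAM, where scores ran from 3.82 to 8.64. The ribosomal protein score had an SD of 0.86 in T-divSLAM and of 0.15 to 0.27 in the other 5 groups. G2/M scores spread most in T-aSLAM (3.05 ± 2.47).

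Markers of other blood and stromal lineages varied between groups. The granulocyte and monocyte score was highest in sSLAM (3.82 ± 1.75) and lowest in T-divSLAM (1.39 ± 1.35), and the score of the 3 basophil and mast cell genes was highest in aSLAM (3.86 ± 1.93). Erythroid scores ran from 1.87 ± 0.70 in T-qSLAM to 3.41 ± 1.09 in aSLAM. Mpo, a neutrophil granule enzyme, averaged 0.05 ± 0.38 in sSLAM and 0.06 ± 0.44 in divSLAM and was listed at 0 in all cells of the other 4 groups. Erythroid (9 genes measured for aSLAM minus sSLAM), lymphoid (6), basophil and mast cell (3) and endothelial or stromal (7) lists had medians of 1.44, -0.22, 0.19 and 0.39 there, against 0.71, 0.52, 0.63 and 0.33 for matched lists. The list of sex chromosome transcripts had a median of -0.77 against 0.79 and that of long-lived nuclear RNA, a sign of RNA quality, -0.99 against 0.75, with Malat1 at -2.75. The sort gate list (6 genes measured) had -0.63 against 1.21, with Kit at 4.26 ± 2.30 in aSLAM and 6.32 ± 2.79 in sSLAM. Slamf1, encoding CD150, averaged between 0.95 and 1.67 in all groups. Of the mitochondrial fission and fusion genes fixed in advance, Dnm1l averaged 2.66 ± 3.20 in sSLAM, 5.41 ± 2.32 in aSLAM, 5.11 ± 2.79 in divSLAM, 2.18 ± 3.08 in T-qSLAM, 3.90 ± 3.11 in T-aSLAM and 3.51 ± 3.05 in T-divSLAM. Opa1 followed a similar order of group means (1.14, 3.33, 2.72, 0.31, 2.46 and 2.46), and Mfn2 lay between 0.72 and 2.32.

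**Figure D4:**
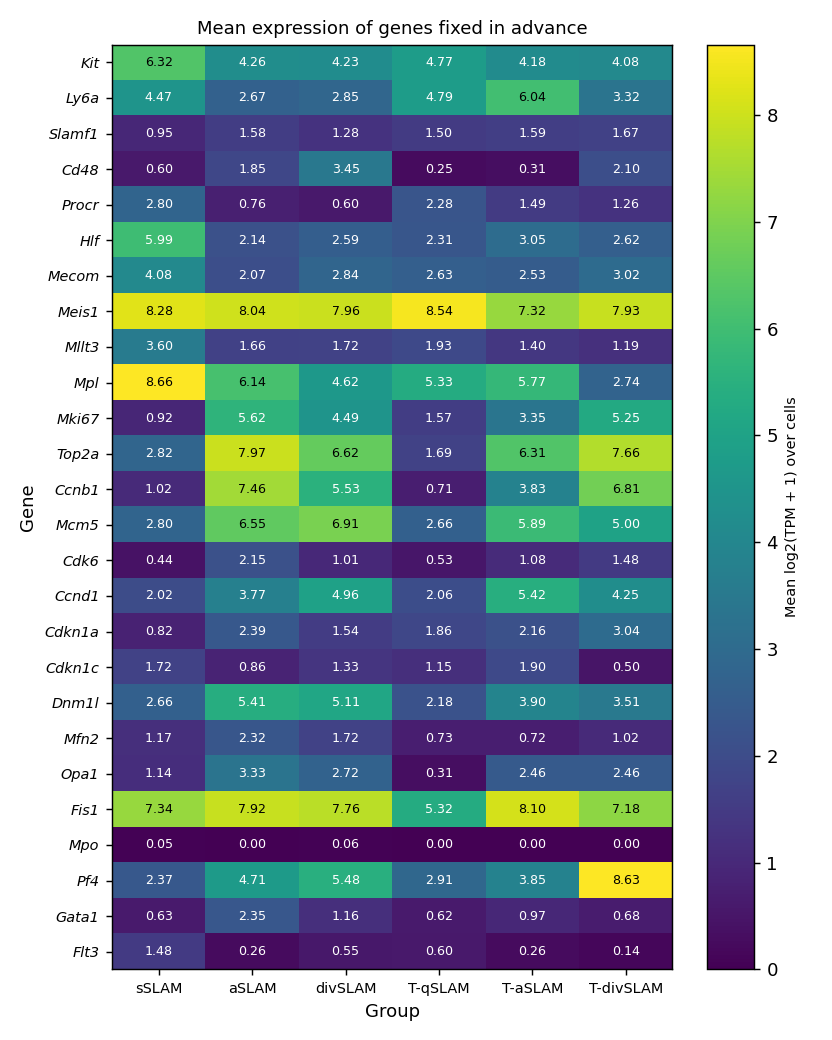
Mean log2(TPM + 1) over cells (colour and printed value) of 26 genes fixed in advance (rows) in the 6 groups (columns). Mpl runs from 8.66 in sSLAM to 2.74 in T-divSLAM, and Pf4 from 2.37 in sSLAM to 8.62 in T-divSLAM.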

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

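The tests of transcript length, of gene number for the respiratory chain, of resemblance to divSLAM, and of shared captures and sequencing runs were chosen only after the result or closely related values had been seen.

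The div minus a difference ran in opposite directions with and without the T label for G2/M genes (-1.35 without T, 0.82 with T, a median per-gene difference of 2.335). It did so as well for genes reported higher in aged stem cells (-0.57 and 0.23, median 0.537), although that median lay within the middle 95% of matched lists (0.128, percentile 97.45). Neither difference between contrasts was tested, since each group is 1 sample. With only the 8 aSLAM cells of capture 092415, the G2/M value was 3.80 and that of the aged-cell list -0.19 (percentile 14.1). The aged-cell value thus depended on which aSLAM cells were used. As the group label of these 8 cells is in doubt, this does not decide whether it holds. At equal gene number the G2/M difference without T was only -0.267 against -0.048 (percentile 4.7), while that with T stayed above matched lists. Without T it was -0.999 with the aSLAM cells of 120215 and -2.757 with the 8 of 092415, whose group label is in doubt.

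Respiratory chain transcripts were lower in T-divSLAM than in T-aSLAM (median -1.51, matched lists -0.81). A general loss of short transcripts, as measured by the trend on median transcript length, is argued against as the whole cause. With that trend removed the median was -1.287 (-1.31 to -1.28 leaving out each gene), still at percentile 0. The median lengths need not be those of the transcripts measured, so part of a length effect could remain. Fewer genes detected per cell stay open: within bins of 500 genes the median was -0.677 (-0.82 to -0.55 leaving out each bin), between the values predicted for and against it. The bin medians ran from -1.91 at 3000 to 3500 genes, with 11 T-divSLAM and 4 T-aSLAM cells, to -0.24 at 5000 to 5500 genes, with 8 and 9. The groups share 0 capture labels, so capture and the biological difference named by the labels cannot be told apart.

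Immediate early transcripts were higher in sSLAM and T-qSLAM than in the other 4 groups. Fewer genes detected per cell are argued against for T-qSLAM, since at equal gene number the median of T-divSLAM minus T-qSLAM was -4.149 (-4.50 to -3.52 leaving out each bin). Sex of the animals is argued against for sSLAM, since among the 20 aSLAM and 54 sSLAM cells with a Y-linked transcript the median was -1.199 (-1.25 to -1.14 leaving out each gene). As 0 other groups share a sequencing run with either, run, capture and handling cannot be told apart from the group. Within the T groups, sex cannot be told apart from the T-qSLAM label. A Y-linked transcript was detected in 41 T-qSLAM cells and in 0 T-aSLAM or T-divSLAM cells. The cell state that the labels name stays open and untested.

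The 8 aSLAM cells of capture 092415 stood apart from the other 32, with G2/M scores of 6.67 ± 0.59 against 4.92 ± 1.41. If the shared capture with divSLAM set their profile, 7 or 8 should have resembled the mean divSLAM cell more than the mean aSLAM cell of 120215; 5 did, compared with 1 of the 32 other aSLAM cells and 47 of 55 divSLAM cells, which does not decide it. Cell cycle stage stays open too: the list of genes reported higher in aged stem cells was higher in the 32 by 1.24, and by 0.929 (0.55 to 1.31 leaving out each gene) in the 12 of them whose G2/M scores lay in the range of the 8. The names of the 8 begin an alphabetical run that continues with divSLAM cells, so a wrong group label stays open as well. No biological explanation was tested.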

How the results depend on the processing

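Comparisons at equal gene number, without the length trend and within cells of one sex were chosen after seeing the data, and so was the value followed here, the list median minus that of matched lists. It replaced the raw list median after many reversals of the latter were seen: of 1052 list calls, the raw median changed sign in 61 (17 at equal gene number, 12 with the ratio of arithmetic means) and the value used here in 10. Of 2928 pairs of a result and an alternative setting, 2811 stayed within a tolerance, 107 moved beyond it and 10 changed sides. For gene lists and gene numbers the tolerance was the SD over cells, for shares the exact interval, and otherwise a fixed margin. It is wide. For G2/M in divSLAM minus aSLAM it was 1.673, and -0.219 at equal gene number (percentile 4.7) counted as unmoved. Only lists outside percentiles 2.5 to 97.5 could change sides, so 2811 is no measure of robustness. Over the 9 differences, 913 of 1052 list calls outside those percentiles stayed there. At equal gene number 50 of 89 stayed. There the G2/M list changed sides for divSLAM minus sSLAM (-0.648), T-aSLAM minus T-qSLAM (-1.05) and T-aSLAM minus aSLAM (0.828), as did cholesterol synthesis for T-aSLAM minus aSLAM (0.076); G1/S moved to 0.225 for divSLAM minus sSLAM and 0.117 for T-aSLAM minus T-qSLAM, and stem cell identity to -0.608 for divSLAM minus sSLAM. The cause was not tested, and these comparisons rest on as few as 9 and 7 cells. For the differences just named, they set the highest cells by genes detected of the group with fewer genes against the lowest of the other. A gene number effect cannot be told apart from that choice of cells. No such comparison was possible for aSLAM minus sSLAM, and lists with fewer than 3 measured genes gave no value. With only the 8 aSLAM cells of 092415, sides changed for divSLAM minus aSLAM in genes reported higher in aged stem cells (0.784), fatty acid oxidation (-0.351) and granulocyte and monocyte markers (-0.059), for T-aSLAM minus aSLAM in the unfolded protein response (0.261) and granulocyte and monocyte markers (-0.47), and the correlation of the contrasts moved to -0.025. The group label of those 8 cells is in doubt. The ratio of arithmetic means turned the aged-cell list in T-divSLAM minus T-aSLAM (-0.161). The cause was not tested.

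Pseudocounts of 0.1 and 10 stretch or shrink the scale by construction. Stem cell identity became -2.976 and -1.007 for aSLAM minus sSLAM, and -2.858 and -1.027 for divSLAM minus sSLAM. Immediate early genes became -3.736 and -1.339 (aSLAM minus sSLAM), -3.82 and -1.59 (divSLAM minus sSLAM), -6.521 and -2.802 (T-aSLAM minus T-qSLAM), and -6.559 and -2.423 (T-divSLAM minus T-qSLAM). Without the filter, which adds undetected members, they were -1.433, -1.404, -3.577 and -3.045. The share of cells with at least 5 G2/M genes was 13.559% in sSLAM and 19.643% in T-qSLAM at 5 TPM, and 84.746%, 62.5% and 100% in sSLAM, T-qSLAM and T-aSLAM above 0. Median-of-ratios rescaling kept 103 of 106 list calls but took the median of all genes for aSLAM minus sSLAM from 0.85 to 0.71. Read depth is unknown, so its limits cannot be stated beyond the genes detected.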

Other observations

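No test was chosen for this part before or after the results were seen, and these values are descriptions. Gzmb and Nkg7, genes of cytotoxic granules, were both higher in T-divSLAM than in T-aSLAM, with Nkg7 at 4.76 ± 4.05 and 2.72 ± 3.98, and Fcer1g at 3.28 ± 4.11 and 0.75 ± 1.97. Gzmb is in the basophil and mast cell list, whose scores were 3.47 ± 1.86 in T-divSLAM and 2.52 ± 1.34 in T-aSLAM. Nkg7 is in the lymphoid list, at 1.15 ± 0.87 and 0.84 ± 0.86, and which cell type these genes reflect was not tested. The cyclin D1 gene Ccnd1 averaged 5.42 ± 2.45 in T-aSLAM, 4.96 ± 2.32 in divSLAM, 4.25 ± 2.99 in T-divSLAM and 3.77 ± 2.56 in aSLAM, compared with 2.02 ± 3.16 in sSLAM and 2.06 ± 2.74 in T-qSLAM. Cdkn1c, encoding the inhibitor p57, averaged 1.90 ± 2.60 in T-aSLAM and 0.50 ± 1.46 in T-divSLAM. Procr, encoding the stem cell surface protein EPCR, averaged 2.80 ± 3.64 in sSLAM and 2.28 ± 3.34 in T-qSLAM and between 0.60 and 1.49 in the other 4 groups.

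Histone H2B transcripts set T-qSLAM apart from all other groups. The mean log2 of the summed TPM over 19 H2B genes was 11.35 ± 0.89 in T-qSLAM, 4.08 ± 3.93 in sSLAM, 6.12 ± 1.54 in aSLAM, 6.61 ± 1.97 in divSLAM, 5.25 ± 2.73 in T-aSLAM and 4.27 ± 3.53 in T-divSLAM. T-qSLAM had low shares of cells with S phase and mitotic transcripts, with Mcm5 in 44.6% and Ccnb1 in 10.7% of cells. No explanation was tested.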
